A study of Homo sapiens with 53 samples.

How the data were processed

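The series studied SBNO2, a Strawberry notch family protein, with PAR-CLIP (photoactivatable ribonucleoside-enhanced crosslinking and immunoprecipitation) and RNA-seq. PAR-CLIP feeds cells 4-thiouridine, crosslinks protein to RNA with ultraviolet light and sequences the RNA that comes down with the protein, and crosslinked uridines are read as T-to-C changes. Per the labels' protocols, HEK293 cells (a human embryonic kidney line) expressed FLAG-HA-tagged SBNO2 from a tetracycline-induced construct, nuclei were isolated before lysis, and the complexes were precipitated with an anti-FLAG antibody. The 5 PAR-CLIP libraries of the 53 samples were analysed. The other 48 are RNA-seq samples and were not analysed here. The libraries carry replicate numbers 1 to 5 in their labels and are called by these numbers. Libraries 1 and 2 held wild-type SBNO2 without stimulation (clones 5 and 2), library 3 the K284A protein without stimulation, library 4 the wild type (clone 5) and library 5 the K284A protein, both after 2 h at 10 ng/ml of a stimulus that the labels write as "INF a". The labels do not say which cytokine this is. The names of the deposited files place libraries 1 and 2 together in an experiment, library 3 in another and libraries 4 and 5 together in the last, so 0 of the 3 experiments held both stimulation states.

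Each deposited table listed the clusters of 1 library, called per library and not on pooled reads. The caller is not given in the sources used here. The submitters' processing notes name bcl2fastq 2.20.0, cutadapt 2.4, Bowtie 1.2.2, Cufflinks 2.2.1 and hg38 for the whole series without assigning steps. Coordinates are in hg38 and count from 1. Per the file headers, each cluster has a count of reads and a count of distinct reads. The count of reads includes copies of the same molecule and was deposited without normalization. No label says whether molecular identifiers were used. The fraction of reads with a T-to-C change was computed by the authors for each cluster. A conversion specificity score, also given by the authors, was not used in any comparison. The smallest cluster held 5 reads, so a gene without a cluster is described as having no cluster listed and is given no upper limit. The annotation class and gene name of each cluster are the authors'. Named mitochondrial clusters were also laid over RefSeq gene spans on the same strand, with a minimum overlap of 5 nt chosen after the data were seen.

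Depth ranged from 660628 reads in clusters (library 2) to 6833440 (library 5), and from 95516 distinct reads (library 3) to 1121114 (library 5). Clusters without a gene name were left out of gene-level library sizes and tests. They held 14.9%, 17.3%, 18.3%, 23.4% and 32.3% of the reads of libraries 1 to 5. Exact 95% binomial intervals were computed for shares of clusters. They cover counting error only, since copies of a molecule are not independent. Nothing in the labels says how far libraries of one protein were separate cultures beyond the clone names, so p-values measure the spread between these libraries.

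Reads were summed per gene name and tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr) in R 4.3.3, with protein and stimulation as additive terms and 2 residual degrees of freedom. A protein by stimulation interaction was tested with 1 residual degree of freedom, and its genes were filtered on its own design. Benjamini-Hochberg adjusted p-values under 0.05 were counted. Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. The 20 lists were small nuclear RNAs, other RNA polymerase III and ribonucleoprotein RNAs, nuclear long non-coding RNAs, splicing factors, interferon-stimulated genes, early TNF and NF-kB genes, immediate-early genes, replication-dependent histones, ribosomal proteins, mitochondrially encoded genes, snoRNA hosts, 7SK and P-TEFb genes, RNA exosome genes, cholesterol synthesis, unfolded protein response, p53 targets, HEK293-typical genes, dermal fibroblast markers, the 60 longest tested genes and the Strawberry notch family. DESeq2 1.42.0 was an alternative. On simulated counts with 200 changed genes and the dispersion of the reads (common dispersion 0.872), the K284A test over 10820 genes recovered 5.97% of 4-fold, 35.8% of 16-fold and 50.0% of 64-fold changes. The stimulation test over 10853 genes recovered 5.97%, 34.3% and 50.0%. With the dispersion of distinct reads (0.215), the K284A test over 4779 genes recovered 25.4%, 76.1% and 83.3%, and the stimulation test over 4557 genes 37.3%, 70.1% and 92.4%. A fit with the experiment as a block, added after the data were seen, estimates K284A against wild type from libraries 4 and 5, with its spread from libraries 1 and 2 (1 residual degree of freedom), and cannot estimate stimulation.

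These designs, the lists and most alternatives were chosen before the data were examined. The rule for named genes took the 10 protein-coding and 10 non-coding genes with the highest mean share of reads in the wild-type libraries, up to 10 called genes per direction with a mean of at least 20 reads, the 5 genes of smallest p per direction where fewer passed, up to 4 tested members per list, and SBNO2 and SBNO1. The rule asks for the same sign in both strata, which an interaction does not have. Genes outside this rule were chosen after their values were seen. Y-linked genes and the RNAs of X inactivation were left out of the named genes.

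No genome sequence was used. Splice-site distances were therefore not computed, intronic clusters were placed by 10% steps of the RefSeq gene span, and sequence was compared with shuffles of the same clusters that keep dinucleotides. RefSeq symbols matched 92.5% of named clusters, and 97.9% of the matched clusters lay inside the RefSeq gene. Clusters were also laid over 443 nuclear tRNA genes of the RefSeq table, which gives no strand. This overlay was added after the data were seen. Overlaps of clusters were found with bedtools 2.31.1, on the same strand and with at least 1 nt shared. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. Near-identical genes (histones, snRNAs, tRNAs, their pseudogenes) can share reads, and values of single members are uncertain.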

Results

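Tagged SBNO2 was precipitated with crosslinked RNA from lysed nuclei of HEK293 cells, and clusters of crosslinked reads were listed for 5 libraries. All 5 held the induced tagged protein, so no library without it gave a background for the clusters. Although nuclei were isolated before lysis, mitochondrial clusters held 6.35%, 12.0%, 15.5%, 11.8% and 9.48% of distinct reads in libraries 1 to 5. Libraries 1 and 2 (wild type) and 3 (K284A) were unstimulated, and libraries 4 (wild type) and 5 (K284A) were stimulated. The deposited tables held 89423, 53313, 40693, 143020 and 298151 clusters in this order, with 1410124, 660628, 1236391, 2979174 and 6833440 reads. Distinct reads numbered 228128, 191524, 95516, 404844 and 1121114, or 1 per 6.18, 3.45, 12.9, 7.36 and 6.10 reads. Clusters covered 3244726, 1929866, 1000927, 4090937 and 7567558 nt. Reads with a T-to-C change made up 73.0%, 70.3%, 82.3%, 88.7% and 81.1% of the total. The K284A protein had 1 library per stimulation state and the stimulated wild type 1, so values of these groups have no replicate error.

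The first question was where in transcripts the protein was crosslinked. Introns held 39.3%, 36.7% and 41.6% of clusters in unstimulated libraries 1 to 3, and 55.2% and 57.4% in stimulated libraries 4 and 5. Coding sequence held 22.6%, 23.4% and 19.3% without stimulation and 9.91% and 8.70% with it. Clusters in 3' UTRs made up 16.8%, 17.4% and 16.1%, against 8.51% and 7.86%. The 5' UTR share lay between 1.93% and 2.50% in all 5 libraries. Exonic clusters (coding sequence and UTRs) averaged 40.9% ± 3.03 (SD, n = 3) without stimulation and 19.5% ± 1.48 (SD, n = 2) with it, a difference of -21.3 percentage points. Intronic clusters averaged 39.2% ± 2.44 (SD, n = 3) and 56.3% ± 1.55 (SD, n = 2), a difference of 17.02 points, which was 8.84 points with reads thinned to the smallest library, where library 5 had 38.2% and library 3 had 41.3%. Without thinning, both differences exceeded the spread between libraries, and 3 libraries against 2 allow no exact p under 0.05. Clusters of 1 distinct read made up 52.7%, 40.2%, 57.6%, 46.9% and 47.6% of clusters in libraries 1 to 5. Of exonic and intronic clusters together, 51.6%, 54.1%, 47.4%, 27.2% and 24.4% were exonic. Among those with at least 5 distinct reads, 93.99%, 95.03%, 80.3%, 62.5% and 57.8% were exonic. Intronic clusters were thus the minority there in every library. The exonic share was lower in the stimulated libraries in both sets. Stimulated and unstimulated libraries came from different experiments.

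The same direction appeared within genes. Among 1552 genes with at least 5 exonic or intronic clusters in every library, the median exonic share was 46.7% without and 18.9% with stimulation. The share was lower in the stimulated libraries in 1425 of these genes, higher in 96 and tied in 31. Between proteins the exonic share was lower for K284A by -5.11 points without stimulation and by -2.09 points with it. The unstimulated difference ran from -32.2 points among clusters of at least 20 reads to -2.06 points among clusters of 20 to 30 nt. The stimulated difference turned to 5.72 points among clusters of at least 20 reads. Library 3 came from another experiment than libraries 1 and 2, its clusters had a median of 23 nt against 39 and 38 nt, and the name of its file calls it combined and carries an adapter label that the other names lack. Neither is explained, and no label says whether its reads were trimmed differently.

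**Figure D1:**
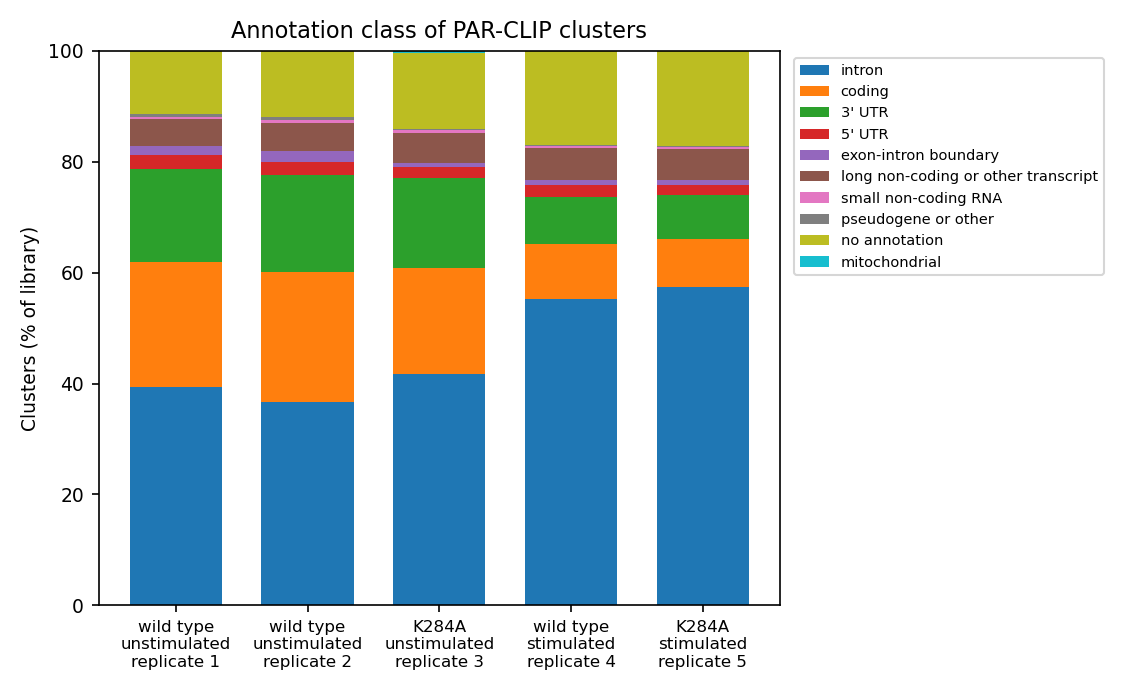
Share of clusters (% of each library) in each annotation class, 1 stacked bar per PAR-CLIP library. Introns take 39.3%, 36.7% and 41.6% of the unstimulated libraries and 55.2% and 57.4% of the stimulated ones.

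Intronic clusters lay more often near gene starts. The first 10% of the gene span held 13.7%, 13.3%, 13.6%, 15.7% and 14.1% of intronic clusters in libraries 1 to 5, where an even spread over the gene gives 10%. The last 10% held 6.15%, 6.99%, 5.66%, 5.94% and 6.26%. The even spread is over whole genes and not over introns, which are not evenly placed. With clusters over tRNA genes and other small RNAs left out, the genes with the highest intronic share of distinct reads in wild-type libraries were ERC1 (chromosome 12, 989959 to 1495933), with 96, 62, 38, 91 and 164 intronic clusters, and NEDD4 (chromosome 15, 55826917 to 55993612), a ubiquitin ligase gene, with 5, 2, 4, 9 and 12. DAZAP1, an RNA-binding protein gene and the next by this share, had 46, 29, 30, 136 and 231 intronic clusters, and AUTS2, after it, had 110, 56, 30, 202 and 385. These 4 genes were chosen after their values were seen. Across 11842 genes, which are not independent replicates, intronic clusters per gene correlated with gene span (Spearman's rho 0.38 to 0.44 per library).

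**Figure D2:**
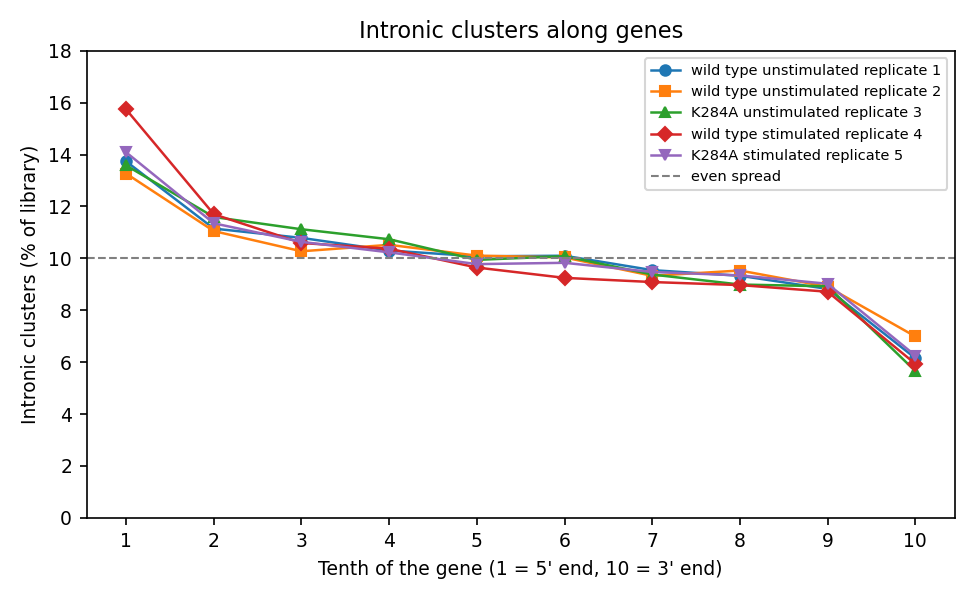
Intronic clusters (% of each library's placed intronic clusters) by 10% steps of the gene span from the 5' to the 3' end, 1 line per library, with the even spread of 10% dashed. The first step holds between 13.3% and 15.7% and the last between 5.66% and 6.99%.

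Mitochondrial transcripts, a vault RNA and reads over tRNA genes under other names were among the named RNAs with the highest wild-type shares, and so was the U12 snRNA without stimulation. Mitochondrial values follow the name given to each cluster, and clusters that reach at least 5 nt into several mitochondrial genes held 15.5%, 6.78%, 52.2%, 32.3% and 41.9% of the named mitochondrial reads in libraries 1 to 5. In library 4, 27373 of the 32689 reads named MT-ND4 came from a cluster that begins in MT-TG and covers MT-ND3. The values of single mitochondrial genes are therefore not levels of those genes alone. Over the 3 wild-type libraries, the mean share of named reads was 1.43% ± 0.197 (SD, n = 3) for MT-ND4, 1.42% ± 0.650 for MT-CO1, 0.793% ± 0.305 for MT-ND5 and 0.662% ± 0.243 for MT-CO2. MT-ATP6 (0.453% ± 0.141), MT-CO3 (0.422% ± 0.418), MT-ND2 (0.325% ± 0.139) and MT-CYB (0.280% ± 0.0913) followed. The non-mitochondrial coding genes of this group were LUC7L2 (0.635% ± 0.155), of whose reads 96.4% lay over a tRNA gene in its intron, and the amino acid transporter gene SLC1A5 (chromosome 19, 46774883 to 46788594; 0.263% ± 0.154). Among non-coding genes MT-RNR2 had 1.26% ± 1.88, a mean that rests on stimulated library 4, with no cluster listed in library 1, 1916 reads in library 2 and 77970 in library 4. VTRNA1-2, a vault RNA (chromosome 5, 140718926 to 140719013), had 0.946% ± 0.380, VTRNA1-1 0.286% ± 0.186, RNU12, the U12 snRNA of the minor spliceosome (chromosome 22, 42615244 to 42615393), 0.547% ± 0.435 (0.446%, 0.754%, 0.0670%, 0.160% and 0.0506% of all distinct reads in libraries 1 to 5), and RNU5D-1, a U5 snRNA, 0.290% ± 0.0995. MT-RNR1 had 0.310% ± 0.538, from library 4 alone, and MT-TS2 0.210% ± 0.186, with no cluster listed in library 4. RP11-352D13.5 had 0.345% ± 0.295, with 6321 and 2744 reads in libraries 1 and 2 and 107 in library 4. RP11-867G23.8 (0.512% ± 0.301) and RP4-561L24.3 (0.209% ± 0.102) drew 100% of their reads from tRNA genes. Clusters named SBNO2 (chromosome 19, 1107638 to 1174268) held 29, 8, 9, 264 and 485 reads. The cells also expressed SBNO2 from the tetracycline-induced construct, and reads of its RNA were not told apart from those of the endogenous gene.

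**Figure D3:**
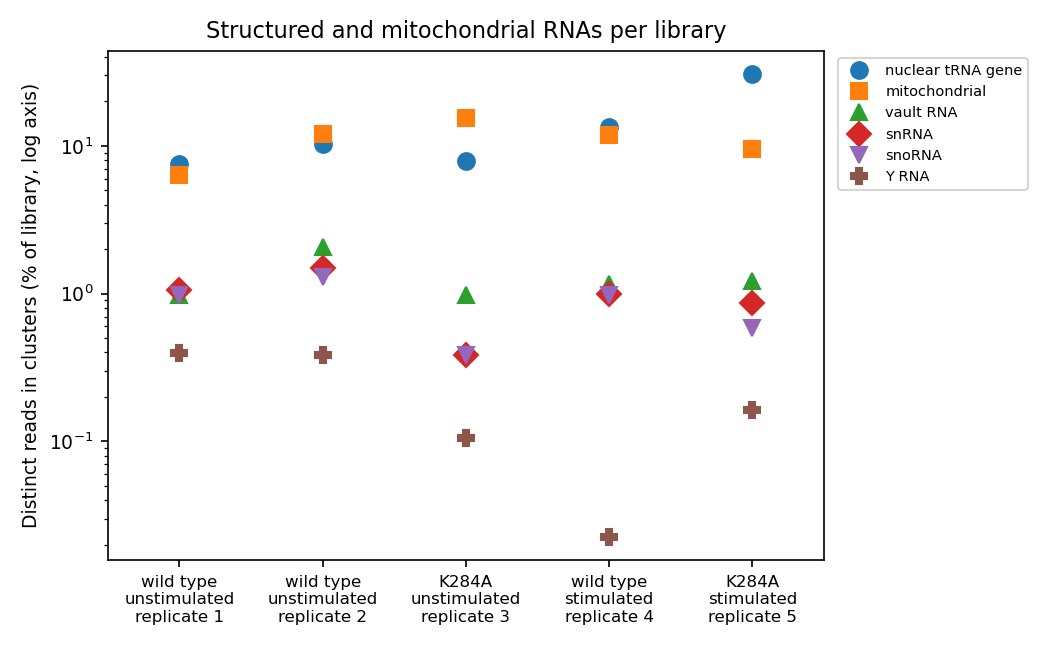
Distinct reads over nuclear tRNA genes, mitochondrial RNA, vault RNA, snRNA, snoRNA and Y RNA (% of all distinct reads in clusters, log axis), 1 point per class and library. Nuclear tRNA genes reach 30.7% in the stimulated K284A library and lie between 7.54% and 13.4% in the other libraries.

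Nuclear tRNA genes took 7.54%, 10.4% and 7.93% of distinct reads in unstimulated libraries 1 to 3, 13.4% in stimulated wild-type library 4 and 30.7% in stimulated K284A library 5. Clusters lay over 183, 187, 203, 269 and 291 tRNA genes, 315 in any library and 105 in all 5. Clusters passing both ends of the gene held 66.4%, 55.5%, 27.4%, 73.2% and 82.2% of tRNA distinct reads. Clusters passing the 3' end of the gene held 81.9%, 87.8%, 80.7%, 96.3% and 97.2% of tRNA distinct reads, and clusters passing the 5' end 81.6%, 67.2%, 37.7%, 76.7% and 85.0%. Clusters that stayed inside the gene held 3.03%, 0.443%, 8.99%, 0.237% and 0.0201%. The authors' annotation gave no class to clusters with 68.2% of these reads and called 21.6% intronic.

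The K284A and wild-type libraries of the stimulated state were compared gene by gene. Of 255 tRNA genes with clusters in both, 216 had a higher share in K284A, with a median log2 ratio of 0.87 (quartiles 0.30 and 1.41). Among 3485 other genes with at least 20 distinct reads in both, 616 were higher and the median was -0.47. All are shares of the same total, so the larger tRNA share in library 5 itself lowers the shares of other genes. TRR-CCT4-1, an arginine tRNA gene (chromosome 7, 139340700 to 139340772) inside an intron of LUC7L2, took 0.444%, 0.664%, 0.178%, 0.607% and 5.28% of distinct reads. LUC7L2 outside this tRNA gene took 0.0133% in library 5 and 0.0141% in library 4. By amino acid, the log2 ratio between stimulated libraries was 2.38 for arginine (1.75 without TRR-CCT4-1), 1.60 for the rarely covered selenocysteine, 1.37 for lysine, 1.32 for tryptophan, 1.31 for serine, 1.19 for isoleucine and -0.32 for glycine tRNA genes. Clusters over tRNA genes covered 26028 nt at 1322 distinct reads per 100 nt in library 5 and 21676 nt at 249.5 in library 4, without scaling for depth, where all clusters held 14.8 and 9.90 per 100 nt. Without stimulation, 29 of 108 tRNA genes had a higher share in K284A than the wild-type mean, with a median log2 ratio of -0.73. These comparisons of shares have no replicate check in K284A.

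**Figure D4:**
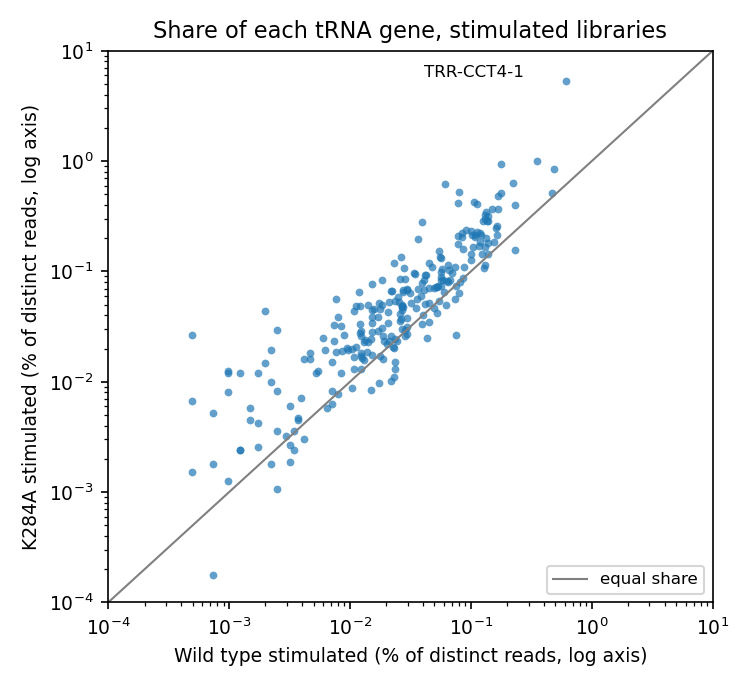
Share of each tRNA gene in stimulated wild-type library 4 (x, % of distinct reads, log axis) and stimulated K284A library 5 (y, % of distinct reads, log axis), 1 point per gene with clusters in both, with the line of equal share. Of the 255 genes, 216 lie above the line, and TRR-CCT4-1 is at 0.607% and 5.28%.

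The K284A and wild-type proteins were then compared gene by gene over all 5 libraries. The edgeR test called 0 of 12509 genes, with 347 at an unadjusted p under 0.05, and DESeq2 called 111. Among genes that did not pass, the smallest p for higher values in K284A belonged to SNORD43 and SNORD96A (2 small nucleolar RNAs) and to SNTG1. SNORD43 had 574 reads in library 3 and 751 in library 5, SNORD96A 79 and 1802, and SNTG1 471 and 91, with no cluster listed for any of the 3 in the wild-type libraries (edgeR adjusted p = 0.149 each). HIST1H4B, a histone H4 gene, had a log2 ratio of 3.02 (SE 0.55), and HES1, a transcriptional repressor gene, 3.15 (SE 0.61), each at an adjusted p of 0.965. On the lower side, RNA5SP202 had 920, 534 and 13 reads in wild-type libraries 1, 2 and 4 and 12 in K284A library 3 (adjusted p = 0.149), with no cluster listed in library 5. SNORD88A, RN7SKP130 and RN7SL151P had clusters in libraries 1 and 2 only, with none listed in wild-type library 4 or in either K284A library. SYP had clusters in libraries 1 and 2, 32 reads in library 4 and none listed in either K284A library (edgeR adjusted p = 0.965 for each of these genes). Leaving out library 1, 2, 3, 4 or 5 gave 8, 34, 16, 47 or 47 calls. With the experiment as a block, the edgeR count was 14 (9 higher, 5 lower), and 0 with the genes kept by the additive filter (198 at an unadjusted p under 0.05) and 0 with distinct reads (122).

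Groups of genes were shifted between proteins at the preset correlation only. The fit joins library 3 against libraries 1 and 2 with library 5 against library 4, and not every list moved alike in both. In libraries 1 to 5, replication-dependent histone genes held 0.697%, 0.571%, 0.617%, 0.153% and 0.280% of named reads. Mitochondrially encoded genes held 6.37%, 10.6%, 15.5%, 9.53% and 9.98%. Ribosomal protein genes held 1.16%, 1.29%, 0.506%, 0.568% and 0.411%, lower in K284A in both states. Of 3485 genes outside tRNA genes with at least 20 distinct reads in libraries 4 and 5, 616 had a higher share in library 5. Their median log2 ratio was -0.47, so a lower stimulated share in K284A was not particular to ribosomal protein genes. Of the 60 longest tested genes, 41 were higher in K284A with a median log2 ratio of 0.52 (camera adjusted p = 1.14e-03; adjusted p = 0.702 with an estimated correlation). Ribosomal protein genes were lower in 55 of 72 members, with a median of -0.75, RPS16 at -2.43 (SE 0.69) and RPL18 at -3.13 (SE 1.10) (camera adjusted p = 2.69e-03; adjusted p = 0.987 with an estimated correlation). Replication-dependent histone genes were higher in 25 of 40, with HIST1H4C at 0.79 (SE 0.59) and HIST1H3D at -0.38 (SE 0.55). Their camera adjusted p was 0.0115, and 0.987 with an estimated correlation. Mitochondrially encoded genes were higher in 13 of 24 (camera adjusted p = 0.0125; adjusted p = 0.987 with an estimated correlation), and with distinct reads this list did not pass (camera adjusted p = 0.0686). Clusters over several of these genes make the member counts depend on naming, as in library 5, where a cluster named MT-ND4 with 98794 reads covers 7 genes. The other 15 tested lists, interferon-stimulated genes and fibroblast markers among them, had camera adjusted p-values of 0.0688 to 0.970. No member of any list was called over all genes, and 1 histone gene was called adjusted over the list alone.

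Stimulated and unstimulated libraries were compared in the same fit. They came from different experiments, so gene and list differences between states cannot be told apart from differences between experiments. The edgeR test called 0 of 12509 genes, with 669 at an unadjusted p under 0.05, and DESeq2 called 558. The smallest p-values for higher values with stimulation belonged to SNORD104 (1982 reads in library 4 and 2747 in library 5; edgeR adjusted p = 0.0795), RNA5SP336 (731 and 967; 0.0853), MT-TT (5718 and 18394; 0.0908) and SNORD11B (1029 and 140; 0.0908), with no cluster listed for these 4 without stimulation. The reads named MT-TT came from 1 cluster in each library, of 716 and 487 nt, with most of its length over MT-CYB. SLC47A1 had 15, 10, 11, 1330 and 6277 reads and a log2 ratio of 6.13 (SE 0.73, adjusted p = 0.0853), and 96.0% of its wild-type reads lay over a tRNA gene. On the lower side, SNORD118, the U8 small nucleolar RNA, had 2926, 1250 and 384 reads without stimulation and no cluster listed with it (adjusted p = 0.0795). RNA5SP202 had 920, 534, 12 and 13 reads in libraries 1 to 4 (adjusted p = 0.0795), and SNORD18C had clusters in libraries 1 to 3 only (adjusted p = 0.148). CTSD, which encodes cathepsin D, had -4.01 (SE 0.63, adjusted p = 0.251) and HIST1H3D, a histone H3 gene, -3.63 (SE 0.61, adjusted p = 0.344). SBNO2, whose reads may include those of the construct, had 3.11 (SE 0.82, adjusted p = 0.704) and SBNO1 0.44 (SE 0.47, adjusted p = 0.938). Leaving out library 1, 2, 3, 4 or 5 gave 15, 94, 127, 11 or 26 calls.

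Histone genes stood lowest among the lists with stimulation. Replication-dependent histone genes were lower in 35 of 40 members, with a median log2 ratio of -1.32, HIST1H3B at -1.58 (SE 0.97) and HIST1H4C at -1.49 (SE 0.62) (camera adjusted p = 1.44e-10; adjusted p = 0.828 with an estimated correlation). Ribosomal protein genes were lower in 43 of 72, with a median log2 ratio of -0.36 and a mean of -0.016. RPSA was at -2.96 (SE 0.88). The camera adjusted p of this list was 6.31e-05, and 0.926 with an estimated correlation. Interferon-stimulated genes were higher in 13 of 20, with a median of 1.02, ISG15 at 1.88 (SE 0.63), TRIM25 at 1.19 (SE 0.68) and ADAR at -0.34 (SE 0.51), and the list did not pass (camera adjusted p = 0.577). Early TNF and NF-kB genes were higher in 11 of 18, with a median of 0.56, and did not pass (camera adjusted p = 0.887). The other 17 tested lists, these 2 included, had camera adjusted p-values of 0.108 to 0.887. Cholesterol synthesis genes, with 12 of 21 higher and a median of 1.04, had the direction down in camera without passing. A positive median is therefore not by itself a shift above the other genes. No list passed the directional fry test or camera with an estimated correlation in either comparison. Fry's test for change in either direction passed with stimulation for the longest genes (adjusted p = 3.05e-03, and 0.0755 with distinct reads) and cholesterol synthesis (adjusted p = 0.0402). No member was called over all genes, and 7 members of 4 tested lists were called adjusted over the list alone, with SBNO2 also called over its own list.

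Whether the K284A effect differed between states was tested by an interaction. The edgeR test called 54 genes (43 higher, 11 lower) of 15049. Of the 54, 51 had no cluster listed in at least 1 library, and 40 had none in K284A library 3, which held the fewest distinct reads. MT-TC had 1344 and 1038 reads in wild-type libraries 1 and 2, 8269 in library 5, and no cluster listed in libraries 3 and 4 (adjusted p = 4.93e-05), in clusters that also reach over MT-TY. MT-RNR1 had 19985, 21254 and 36153 reads in libraries 3, 4 and 5 and none listed in 1 and 2 (adjusted p = 2.70e-03). With the genes kept by the additive filter the count was 0, and with distinct reads also 0, both settings chosen after the data were seen.

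Clusters were largely private to a library. Of regions made by merging clusters, 93.1% had a cluster in 1 library and 594 regions had one in all 5, of which 209 were coding, 113 in 3' UTRs and 100 over tRNA genes. The unstimulated wild-type libraries 1 and 2 shared 10.9% of the smaller set's clusters, against 3.81% after a shift by 1000 nt. Libraries 4 and 5 shared 10.5%, against 5.53% after the shift. The 10 pairs ranged from 6.46% to 13.4%, and after the shift from 2.06% to 6.80%. Among clusters with at least 5 distinct reads the share for libraries 1 and 2 was 44.0%. Reads per gene correlated between libraries with Spearman's rho of 0.65 to 0.83 across 19663 genes, which are not independent replicates.

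Cluster sequences held 29.1%, 29.8%, 32.3%, 28.4% and 30.5% uridine in libraries 1 to 5. PAR-CLIP clusters are called from T-to-C changes, so uridine is present by construction. Against shuffles that keep dinucleotides, the leading 5-mers were GUGGC (mean log2 ratio 0.66), GAGGA (0.65) and CGUGG (0.63).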

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

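All tests of explanations in this part were chosen after the results were seen.

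The interaction test called 54 genes whose K284A effect differed between stimulation states, with 1 library in 3 of the 4 groups and a spread that comes from libraries 1 and 2 alone. Of the calls, 51 had no cluster listed in at least 1 library, and the count was 0 with the genes kept by the additive filter and 0 with distinct reads, so a difference between states is not established. The named genes with a higher K284A effect under stimulation were MT-TC (adjusted p = 4.93e-05), MT-TW (0.000174), SNORD110 (0.000362), MIR19B1 (0.000516), AC079776.2 (0.0205), RNU2-59P (0.0274), RN7SKP163 (0.0298), RNY4 (0.0305), SNORD72 (0.0317) and TOMM22 (0.0404). Those with a lower effect were RMRP (0.00258), MT-RNR1 (0.0027), RN7SK (0.00356), RNU11 (0.00623), RPPH1 (0.00676), RN7SL634P (0.0069), RP11-25K21.6 (0.0196), RN7SL598P (0.0262), RN7SL2 (0.0406) and RNU2-52P (0.0423). None of the genes named with a higher effect had a cluster listed in library 3 or 4. Their higher effect rests on this absence. Reads named MT-TC came from clusters that also reach over MT-TY, and 2442 of the library 5 reads named MT-TW from a cluster with most of its length over MT-ND2. Values of RN7SL and RNU2 copies and of RN7SKP163 are uncertain because near-identical genes share reads. RP11-25K21.6 had 99.5% of its wild-type reads over a tRNA gene.

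Of the named genes with a lower effect, 9 non-coding RNAs had clusters in libraries 3, 4 and 5 and none listed in unstimulated wild-type libraries 1 and 2. Among them were RN7SK (7SK, which holds the elongation factor P-TEFb inactive), RMRP and RPPH1 (RNAs of RNase MRP and RNase P), RNU11 of the minor spliceosome and the mitochondrial rRNA MT-RNR1. For these 5, each with at least 100 distinct reads in every other library, the lowest share elsewhere predicts at least 147 distinct reads in library 1 or 2, which argues against fewer reads as the cause. The same holds for RN7SL2 (37.2), RNU2-52P (17.03) and RN7SL634P (11.4), whose reads may be shared with near-identical copies, while for RN7SL598P (6.15) low depth cannot be told apart from absence. Clusters under another name at these places numbered 0. The experiments with an unstimulated wild-type library numbered 1, so a difference between experiments, in removal of abundant RNAs for example, could account for the absence and stays open, as does a property of the protein in this state.

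The tRNA gene share was 30.7% in stimulated K284A library 5 and 13.4% in library 4. In percentage points this was the largest difference between these libraries among the structured RNA classes compared. By ratio, Y RNA (0.0225% in library 4 and 0.163% in library 5) and 7SL RNA (0.222% and 0.0376%) differed more. Reads per distinct read were 6.22 over tRNA genes and 6.10 in the whole library. Distinct reads are not known to be separate molecules, since no label says whether molecular identifiers were used. PCR copies of few molecules are therefore not judged by this ratio. Without TRR-CCT4-1, the most covered gene, the share was 26.8%. Over 3 vault RNAs, 7SK, RMRP and RPPH1, the median log2 ratio was -0.19 (SD 0.85), against 1.1999 for tRNA genes. RPPH1 alone had 1.197. These RNAs leave out Y RNA and 7SL RNA, also RNA polymerase III transcripts, which moved in opposite directions. The preset list of other RNA polymerase III and ribonucleoprotein RNAs held 1.53% of named reads in library 4 and 2.45% in library 5. Such values argue against an equal shift of all RNA polymerase III transcripts, but not against a shift of some of them. An effect of the substitution may exist under stimulation, but the unstimulated K284A share of 7.93% lies between the wild-type values of 7.54% and 10.4%. With 1 stimulated K284A library it cannot be told apart from a property of that library.

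The lower exonic share in stimulated libraries held within 91.8% of the 1552 genes compared, which argues against other genes being crosslinked. It was -20.9 points with distinct reads and -16.3 points with reads thinned to the smallest library, and -19.3 points among clusters of 20 to 30 nt, so depth and cluster length do not account for the whole of it. The experiments that held both states numbered 0, and stimulation and a difference between experiments cannot be told apart. A stimulation effect of the kind the design names may underlie it and remains untested apart from the experiment.

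Signal also appeared in data outside the gene comparisons. Clusters on the scaffold KI270733.1 held 129, 10, 19, 2042 and 391 distinct reads in libraries 1 to 5 (0.0565%, 0.00522%, 0.0199%, 0.504% and 0.0349% of all distinct reads). Unnamed clusters on the minus strand of the mitochondrial chromosome held 1970, 2822, 1198, 3153 and 9483 (0.864%, 1.47%, 1.25%, 0.779% and 0.846%).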

How the results depend on the processing

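Distinct-read counting, tRNA genes counted apart, thinning, equal cluster numbers, minimum distinct reads, the 20 to 30 nt range, the experiment block and the additive filter for the interaction were tested only after the data were seen. By replicate number, no paired analysis was possible because no replicate number is shared between groups. Wild-type libraries 1 and 4, from different experiments, share a clone, and a fit pairing stimulation by clone was not run. A block on the experiment was possible for K284A, giving 14 calls, 0 with the genes kept by the additive filter (198 at an unadjusted p under 0.05) and 0 with distinct reads (122). Where a value moved, the cause was not tested. The exonic and intronic differences between stimulation states kept their sign in every setting run, and the differences between proteins did not, except the unstimulated exonic one. On counts simulated anew with the spread of the reads, the K284A test recovered 1.49%, 13.4% and 37.9% of 4-fold, 16-fold and 64-fold changes, below the earlier draw. With 4 times the reads it recovered 2.99%, 31.3% and 42.4%, and with a dispersion of 0.05 in place of the measured ones 95.5%, 94.0% and 97.0%. For stimulation these were 4.48%, 34.3% and 60.6%, then 1.49%, 35.8% and 45.5%, then 88.1%, 95.5% and 97.0%. In these simulations the lower dispersion raised recovery more than 4 times the reads did. The dispersion was held at its measured values when reads were added, and draws of 1 setting differed, so what depth limits was not settled.

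For K284A the edgeR count of 0 (347 genes at an unadjusted p under 0.05) became 111 with DESeq2, 72 without a filter, 1 with intronic clusters, 7 with DESeq2 on distinct reads and 8 to 47 when 1 library was left out. For stimulation the edgeR count of 0 (669 at an unadjusted p under 0.05) became 558 with DESeq2, 6 without TMM, 126 without a filter, 25 with clusters per gene, 12 with at least 2 T-to-C positions, 12 with distinct reads (59 with DESeq2) and 11 to 127 when 1 library was left out. The interaction count of 54 became 283 without a filter, 8 with RLE factors, 0 with the additive filter, 0 with distinct reads and 0 with tRNA genes also apart. Leaving out libraries gives no value for it, since without library 1 or 2 no residual degrees of freedom remain and without library 3, 4 or 5 the interaction cannot be estimated. The lists past the threshold numbered 4 for K284A (3 with distinct reads) and 2 for stimulation (2 with distinct reads), and 0 in both with an estimated correlation and 0 with directional fry, for all reads and for distinct reads. Fry in either direction passed with stimulation for the longest genes (3.05e-03, and 0.0755 with distinct reads) and cholesterol synthesis (0.0402, and 0.01003 with distinct reads).

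The exonic difference between states (-21.3 points) was -33.1 with at least 2 T-to-C positions, -33.9 with at least 20 reads, -16.4 with equal cluster numbers, -26.4 with at least 2 distinct reads, -16.3 with thinned reads and -23.0 to -20.1 when 1 library was left out. The intronic difference (17.02) was 29.2, 31.3, 12.8, 22.1 and 8.84 in the same order, 12.5 by distinct reads and 15.8 to 18.2 when 1 library was left out.

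Between proteins, in the order reads, at least 2 T-to-C positions, at least 20 reads, distinct reads, equal cluster numbers and thinned reads, the unstimulated exonic difference (-5.11) was -11.1, -8.77, -32.2, -11.3, -13.2 and -8.98, and the stimulated one (-2.09) -5.06, -5.08, 5.72, -4.41, 5.74 and 8.22. The intronic one was 6.46, -2.36, 30.7, 6.41, 10.5 and 6.55 without stimulation (3.59) and -3.05, 8.48, -5.05, -0.929, -4.80 and -15.2 with it (2.198). With at least 2 distinct reads, thinned distinct reads and 20 to 30 nt, the unstimulated exonic difference was -10.9, -9.14 and -2.06 and the intronic one 7.05, 7.06 and 1.72. The stimulated exonic one was -0.802 with thinned distinct reads.

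The overlap of libraries 1 and 2 (10.9%) was 8.94% with at least 50% of the shorter cluster, 9.94% with equal cluster numbers and 44.0% with at least 5 distinct reads. Uridine (30.04%) was 28.3% in the 10000 clusters with most reads. The tRNA share difference between stimulated libraries (17.3 points) was 20.6 by all reads and 13.997 without the most covered gene. Of the other values, 27 for overlap, 6 for intron position and 3 for composition moved beyond their spread, and 4 for position and 2 for composition stayed within it.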

Other observations

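Counting distinct reads in place of all reads, a choice made after the data were seen, gave 12 stimulation calls. Stimulated and unstimulated libraries came from different experiments, so these calls cannot be told apart from differences between experiments. SLC47A1, with 96.0% of its wild-type reads over a tRNA gene, had a log2 ratio of 6.29 (adjusted p = 0.0411). The log2 ratio was 6.21 for SNORD46, a small nucleolar RNA, 3.55 for FGF18, a growth factor gene, and -4.06 for CTSD, which encodes cathepsin D. SNORD118, the U8 small nucleolar RNA, had 486, 408 and 61 distinct reads in libraries 1 to 3 and no cluster listed in libraries 4 and 5, and SNORD104 had 295 and 480 in libraries 4 and 5 and none listed in the others. Leaving out library 1, 2, 3, 4 or 5 gave 10, 45, 59, 27 or 0 calls.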
